A study of Caenorhabditis elegans with 2 samples.

How the data were processed

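The series holds peak lists from 2 biological replicates of an anti-GFP immunoprecipitation of DAF-16, both in 1 group, per the labels. For each of the genome builds ce10 and ce11 the authors deposited 4 lists: one per replicate, one called on both replicates pooled, and the optimal set. The optimal set was thresholded by the irreproducible discovery rate (IDR), a measure of how alike peaks rank in replicates. On ce11 these hold 28175, 22676, 30000 and 1489 entries. The replicate and pooled lists hold peaks and background, made as input for that threshold. The aligner, the peak caller and the threshold are not given in the sources used here. The deposited lists have no headers. The 1489 optimal entries were the 1489 highest-signal entries of the pooled list. Single entries could rank unlike in the replicates, as the unc-60 peak did at 720 and 5582.

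The signal per peak is the authors' deposited value, and the labels name a possible control. Its scale is not stated, so it was used only to rank and describe peaks within a list. The deposited −log10 q-value has one highest value per list, shared by 1173 entries of the pooled list, and was not used for ranking. Most optimal entries (1289) were 420 bp wide. A list that holds no counts gives no depth, and intervals given here cover the counting of peaks or genes only. One ce10 entry of replicate 2 had a damaged start, which was rebuilt from its end and summit offset. Several entries can share an interval: 21 optimal entries repeated one, and the 25 mitochondrial entries fell in 5 intervals.

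Sequence and genes came from the WBcel235 assembly, which is ce11, with Ensembl annotation. The ce10 lists were used only for checks that need no reference. Analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. A gene was called bound when an optimal summit lay 1000 bp upstream to 500 bp downstream of one of its 29314 transcript starts. Motifs were searched on both strands in 101 bp windows centred on summits and 500 bp to each side, and 1 entry too near a chromosome end was left out. The McNemar test sets each summit against 1 flank drawn with a fixed seed. The 7-mer search used both flanks. Circular shifts and redraws numbered 10000, and the rank correlation had 100000 resamples. Shares have exact (Clopper-Pearson) 95% intervals.

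Tests, lists and most alternatives were fixed before the data were examined. The alternatives covered the overlap rule, the number of peaks, the build, the promoter window, the peak to gene rule, the background, the motif window and each replicate left out, for which the other replicate's highest-signal peaks took the place of the optimal set. Alternatives without mitochondrial entries or without peaks at small RNA genes, and other draws of the flank, were chosen after the data were seen. Named genes were those whose promoter held one of the 20 highest optimal peaks, the 4 bound members of each list with the highest signal, and ges-1, daf-16, unc-119, sod-3, mtl-1, dod-3, daf-2, elt-2 and skn-1 whether bound or not.

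The statistics were tested on simulated peak sets. With 60% of 1400 peaks planted as shared, 60.4% were found. With none planted, 0 7-mers and 0 lists were called, and 4 of 4 lists planted at 30% bound were recovered. The simulated peaks lay at random positions, so a difference in base composition between summits and flanks was not simulated. Lists planted at lower shares were not tried. No untagged or input library was analysed here, so signal that does not depend on the tagged protein could not be measured.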

Results

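Chromatin immunoprecipitation followed by sequencing was used to map where the forkhead (FOXO) transcription factor DAF-16, the main transcriptional output of the insulin-like pathway of Caenorhabditis elegans, was recovered on the genome. The animals were hermaphrodite L4 larvae of strain ZM8745, collected 54 hours after synchronization. They lacked their own daf-16 through the mu86 deletion, carried the e1370 allele of the insulin receptor gene daf-2, and expressed GFP-tagged DAF-16 from the ges-1 promoter, which drives expression in the intestine. Whole animals were used, with an antibody against GFP. The 2 samples were biological replicates of 1 group, so no comparison between conditions was possible. The labels disagree on which end of the protein carried the tag. The deposited lists hold peak positions and signals and no read counts, so the sequencing depth is unknown. Coordinates are on ce11.

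The optimal set held 1489 entries, of which 1464 were on the 6 nuclear chromosomes and 25 on the mitochondrial chromosome. The mitochondrial entries held the 22 highest signals, so all 20 of the highest entries, from which genes were to be named, were mitochondrial and named no nuclear gene. The highest mitochondrial signal was 9154 and the highest nuclear one 556.4, in the authors' signal per peak. The 20 highest nuclear peaks, chosen after values were seen, included 7 within 100 bp of a small nucleolar RNA gene, 2 by transfer RNA genes and 8 in the promoter window of a protein-coding gene. The highest lay in an intron of pxn-1 on chromosome V, from 8500395 to 8500705, by the small nucleolar RNA gene ZK994.7. The promoters of rpl-3 and rpl-15, which encode proteins of the large ribosomal subunit, held the nuclear peaks with signals of 426.8 and 378.9. The rpl-3 peak, on chromosome III from 3867430 to 3867718, had its summit 290 bp from the nearest transcript start, and the rpl-15 peak, on chromosome IV from 654818 to 655047, had it 384 bp away.

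The first question was whether both replicates recovered the same places. Of the 1489 highest-signal peaks of replicate 1, 1044 overlapped one of the 1489 highest of replicate 2 by at least 1 bp, a share of 70.1% with an exact 95% interval from 67.7% to 72.4%. Circular shifts of the replicate 2 peaks along each chromosome gave a mean of 43.04 overlaps and at most 174 in 10000 shifts. With nuclear peaks only, chosen after the data were seen, the share was 69.7% and the mean by chance 18.12. The mitochondrial entries of the optimal set cover 89.7% of their chromosome. The one-sided permutation p was 1e-04, the smallest these shifts can give. Across the 1482 optimal peaks found in both lists, the signals had a Spearman rho of 0.601 (two-sided permutation test, p = 1e-05, the smallest 100000 resamples can give). This correlation is across peaks, which are not independent replicates. The optimal set was itself made from both replicates.

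**Figure D1:**
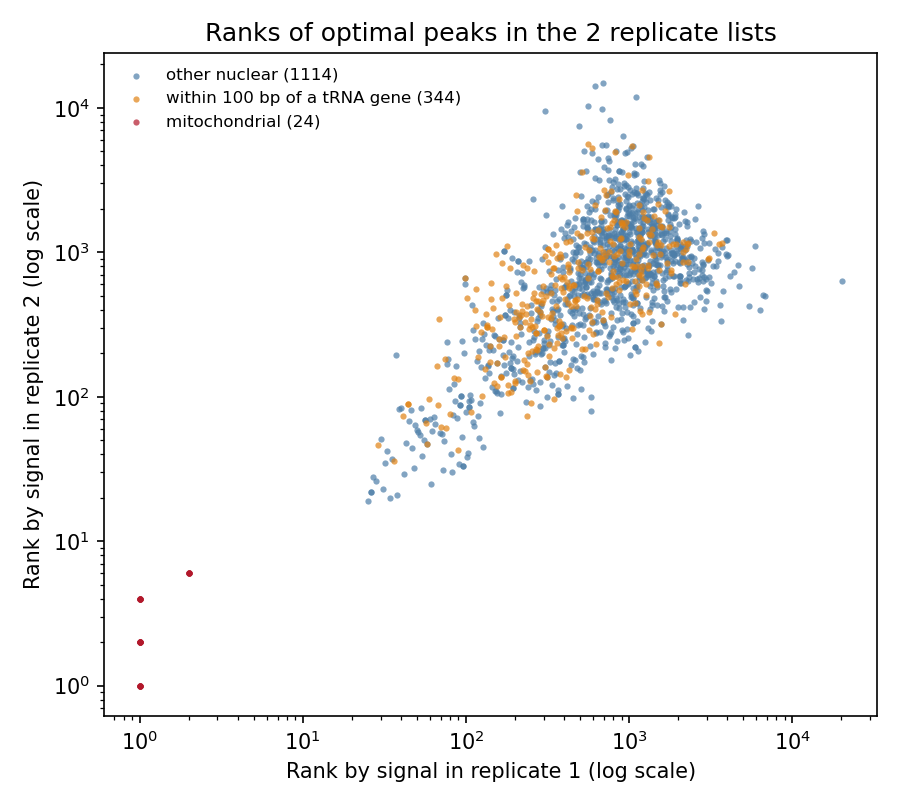
Rank of each optimal peak by signal in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), 1 point per peak found in both lists, coloured by place. Rank 1 is the highest signal. Mitochondrial entries lie at the ranks nearest 1 in both lists, and rho was 0.601 across the 1482 peaks.

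Promoters of protein-coding genes held 703 of the 1489 optimal summits, counting from 1000 bp upstream to 500 bp downstream of a transcript start. This was 47.2%, against 30.5% for summits redrawn at random within their chromosome, a 1.55-fold excess (one-sided permutation test with 10000 redraws, p = 1e-04, the smallest possible). Lower-ranked peaks of the pooled list already had 39.2% at promoters, and the excess over them was 1.204-fold (Fisher's exact test, p = 1.25e-09). Coding exons held 68 of the 1464 nuclear summits, 4.64% with an exact interval from 3.62% to 5.85%, where redraws gave 24.1%. Positions outside protein-coding genes held 925, or 63.2%, against 37.9% by redraws, and 5' UTRs held 46, against a mean of 20.3. Introns held 395, against a mean of 488. Each of these classes differed from the redraws with an adjusted p of 2.44e-04 (two-sided permutation test, Benjamini-Hochberg adjustment over 11 classes, with 2e-04 the smallest p before adjustment).

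Genes of small non-coding RNAs made up much of the set. Within 100 bp of a transfer RNA gene lay 346 nuclear summits, 23.6% with an exact interval from 21.5% to 25.9%, against a mean of 2.84 in the redraws. Small nucleolar RNA genes had 75 summits, against a mean of 1.62, and small nuclear RNA genes, whose products act in splicing, had 27, against a mean of 0.517. Genes annotated as other non-coding RNA had 362, against a mean of 37.1, and 248 of these were also by a gene of the preceding classes. All of these passed the same permutation test (adjusted p = 2.44e-04). MicroRNA genes had 5, against a mean of 1.15 (permutation test, adjusted p = 0.0114). Of 612 nuclear transfer RNA genes, 358 had an optimal summit within that distance, 58.5% with an exact interval from 54.5% to 62.4%. The share was 55.2% in the replicate 1 top set and 53.8% in that of replicate 2. This distance and these classes were chosen after the data were seen.

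The sequence under the summits was then searched for 2 elements linked to DAF-16. TGATAAG, the DAF-16 associated element, which is also a site for GATA factors, lay within 50 bp of 129 of 1488 summits. This was 8.67%, with an exact interval from 7.29% to 10.2%, against 1.65% of windows 500 bp to the sides, a 5.26-fold difference (exact McNemar test, two-sided, p = 2.55e-20). The 703 promoter summits were also set against a window each, drawn at the same distance from a start of a gene with no peak. TGATAAG was at 8.82% of these summits and 3.13% of the drawn windows, a 2.82-fold difference (Fisher's exact test, p = 8.01e-06). At all 1488 summits the shorter GATA core TGATAA was 1.77-fold over the flanks (exact McNemar test, p = 2.95e-10). At the 346 peaks by transfer RNA genes TGATAAG was at 3.18% of summits and 2.17% of flanks (exact McNemar test, p = 0.210, and under 0.05 in 3 of 1000 draws of the flank, chosen after the data were seen). The DAF-16 binding element TRTTTAC, where R is A or G, was present at 78 summits, 5.24% with an exact interval from 4.17% to 6.50%, against 3.66% in the flanks. The exact McNemar test gave p = 0.0416 for this 1.43-fold difference, and that p depended on which flank was drawn for each peak. Over 1000 other draws, chosen after the data were seen, it ran from 3.10e-04 to 0.803 and was under 0.05 in 529. TRTTTAC was 1.52-fold over the lower-ranked part of the pooled list, a background that needs no such draw (Fisher's exact test, p = 7.47e-04). At the 703 promoter summits it was at 5.69%, 1.82-fold over the drawn windows of genes with no peak (Fisher's exact test, p = 0.0265). Those windows were drawn at random with a fixed seed, so this p may also depend on the draw. At the 560 promoter summits not by small RNA genes, chosen after the data were seen, TRTTTAC was 1.29-fold over the flanks (exact McNemar test, p = 0.512). There its TGTTTAC form was at 4.46% of summits and 1.25% of flanks (exact McNemar test, p = 0.00333). Its TATTTAC form was at 1.61% and 3.30% (exact McNemar test, p = 0.0872). Other draws of the flank were not made for these 560 summits. The TGTTTAC form was present at 4.099% of all 1488 summits and 1.18% of flanks, a 3.49-fold difference (exact McNemar test, p = 6.11e-07), and the TATTTAC form at 1.21% and 2.52%. The TGTTTAC difference passed in 1000 of 1000 draws of the flank, also chosen after the data were seen. At 1263 of the 1464 nuclear summits, among them those at rpl-3 and rpl-15, neither TGATAAG nor TRTTTAC lay within 50 bp. Of the 20 highest nuclear peaks, 2 had TRTTTAC.

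**Figure D2:**
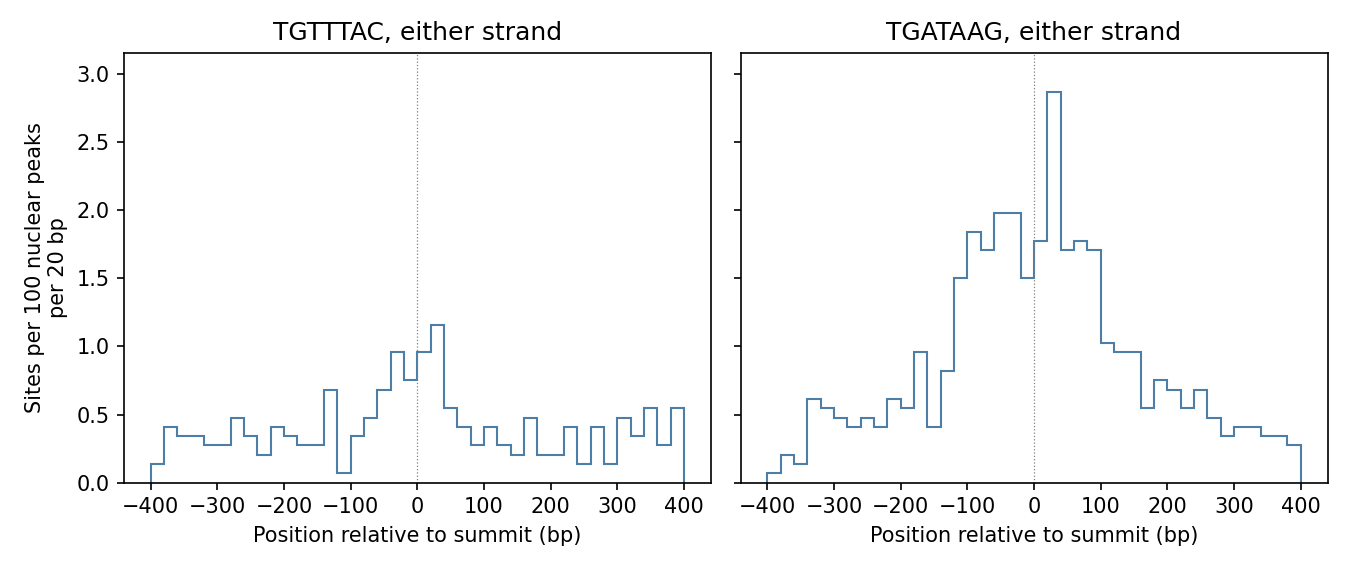
Sites of TGTTTAC (left) and TGATAAG (right), on either strand, per 100 nuclear peaks in each 20 bp bin (y axis) by position from the summit in bp (x axis). TGATAAG reached 2.87 sites per 100 peaks from 20 to 40 bp, and TGTTTAC reached 1.16 there.

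A search over all 7-mers, with no motif given, found 1212 of 8192 present in more summit windows than flank windows and 680 in fewer (Fisher's exact test, adjusted p under 0.05). Among those in fewer, AAAAATT had the lowest adjusted p, at 7.80% of summits and 21.7% of flanks (adjusted exact p = 5.08e-31). A difference in base composition was not separated from these counts. Overlapping 7-mers of 1 sequence count more than once, and the test ignores the pairing of summit and flanks. The lowest adjusted p was that of GGTTCGA, at 10.1% of summits and 0.941% of flanks (adjusted exact p = 1.34e-42). Without peaks at transfer, small nucleolar and small nuclear RNA genes, an alternative chosen after the data were seen, 613 7-mers were more frequent at summits. GGTTCGA was then at 1.48% of summits and 0.787% of flanks (adjusted exact p = 0.283). TGATAAG then had the lowest adjusted p among those enriched, at 11.6% of summits and 1.62% of flanks (adjusted exact p = 4.38e-27). GACGCAG followed at 9.06% and 0.886% (adjusted exact p = 3.74e-25), and GAGAGAG was at 9.55% and 1.57% (adjusted exact p = 2.52e-20).

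An optimal summit lay in the promoter window of 836 of 19973 protein-coding genes, or 4.19%. Among 25 lists fixed before the data were examined, 5 had a higher bound share than other genes and 2 a lower one (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment over the lists). Heat shock proteins and chaperones had 9 bound of 28 genes, 32.1% against 4.15% of other genes (adjusted exact p = 1.06e-05). This ratio of 7.75 was 3.68 by the nearest transcript start (adjusted exact p = 0.0373) and 15.3 in the higher-signal 744 peaks (adjusted exact p = 9.07e-07). They included hsp-3, a chaperone of the endoplasmic reticulum, with a signal of 226.7 and its summit 27 bp from the transcript start, the mitochondrial chaperonin gene hsp-60 with a signal of 189.1, unc-23 with 170.0 and hsp-110 with 161.7. Ribosomal protein genes had 16 bound of 78 (20.5%, adjusted exact p = 1.45e-06), led by rpl-3, rpl-15, rpl-20 and rpl-35, and their ratio to other genes was 4.98, or 7.58 in the higher-signal 744 peaks. Nuclear genes of the mitochondrial respiratory chain had 7 of 34 (20.6%, adjusted exact p = 0.00274), among them the cytochrome c oxidase genes cox-5A with a signal of 199.6 and cox-5B with 132.3. Autophagy and lysosome genes had 6 of 33 (18.2%, adjusted exact p = 0.0111), among them lgg-2 and lgg-1, which encode Atg8 family proteins, with signals of 154.7 and 109.2, and the cathepsin L gene cpl-1 with 116.6. The intestine list had 6 of 47 (12.8%, adjusted exact p = 0.0469), with a ratio to other genes of 3.065. Its call was lost in the higher-signal 744 peaks (ratio 2.24, adjusted exact p = 0.941), without replicate 2 (2.60, adjusted exact p = 0.133) and against random lists matched on upstream distance (3.08, permutation test, adjusted p = 0.0886). Chemoreceptor genes had 10 of 1243 (0.804%, adjusted exact p = 1.12e-11) and C-type lectin genes 2 of 237 (0.844%, adjusted exact p = 0.0202), both lower than other genes. The chemoreceptor ratio to other genes was 0.182, and 0.111 without replicate 2 (adjusted exact p = 1.24e-14). Without peaks at transfer, small nucleolar and small nuclear RNA genes it was 0.110 and that of the lectins 0 (adjusted exact p = 3.13e-12 and 0.00285). The autophagy and lysosome ratio was 4.37, and the list did not pass in the higher-signal 744 peaks, with a ratio of 1.59 (adjusted exact p = 0.961), or by the nearest transcript start, with 3.12 (adjusted exact p = 0.0574). The lectin ratio was 0.1997, and that list did not pass in the higher-signal 744 peaks, with 0.439 (adjusted exact p = 0.961), or without replicate 2, with 0.306 (adjusted exact p = 0.0722). The clec-126 and clec-57 peaks lay by a transfer RNA gene and a small nuclear RNA gene.

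**Figure D3:**
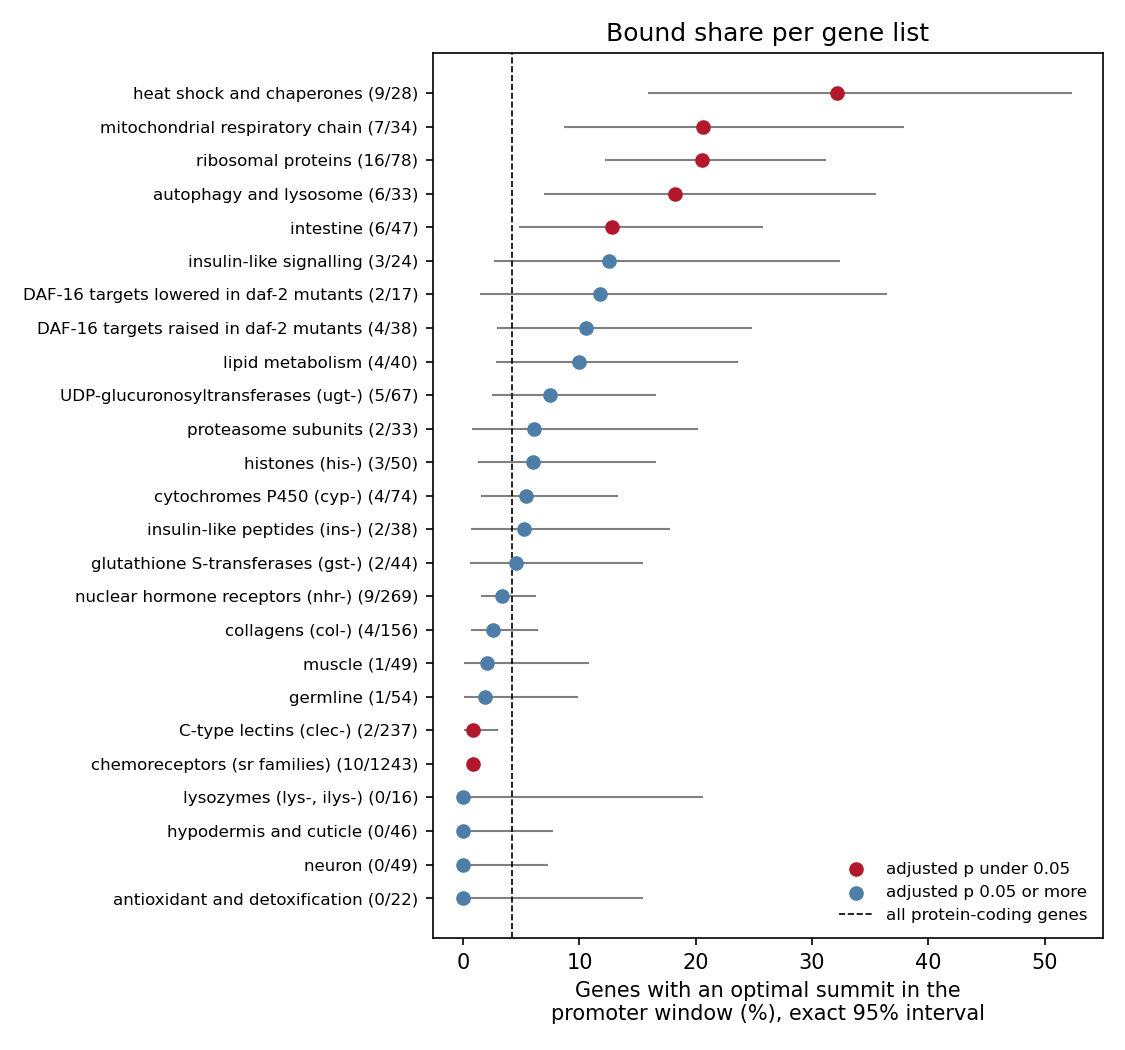
Percent of each list's genes with an optimal summit in the promoter window (x axis), with exact 95% intervals as bars and bound and total genes in brackets. The dashed line is the 4.19% of all protein-coding genes, and heat shock proteins and chaperones stood highest at 32.1%.

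In this promoter window, known DAF-16 targets did not pass the test as lists. Of 38 genes raised in daf-2 mutants, 4 were bound (10.5%, exact interval from 2.94% to 24.8%, adjusted exact p = 0.212). These were icl-1, which encodes an enzyme of the glyoxylate cycle, with a signal of 118.9, dod-3 with 117.1, dod-6 with 102.7 and the phosphoenolpyruvate carboxykinase gene pck-2 with 89.30. The list passed by the nearest transcript start (ratio 3.26, adjusted exact p = 0.0373), and in the higher-signal 744 peaks its ratio was 0. Of 17 lowered targets, the yolk protein gene vit-2 and the insulin-like peptide gene ins-7 were bound (11.8%, adjusted exact p = 0.358). Their ratio to other genes was 2.82, and 1.41 without replicate 1 and 1.43 without replicate 2, with ins-7 at ranks 1797 and 2107 of the single replicates. Of 24 insulin-like signalling genes, ftt-2, rict-1 and ins-7 were bound (adjusted exact p = 0.212), and of 40 lipid metabolism genes 4 were, namely dgat-2, elo-6, fat-4 and plin-1 (adjusted exact p = 0.212). With 2000 bp upstream both lists passed (adjusted exact p = 0.00569 and 0.00202), as lipid metabolism did by the nearest start (adjusted exact p = 0.0381), and with 500 bp upstream the signalling ratio went from 2.99 to 1.33 (adjusted exact p = 0.744). Of 22 antioxidant and detoxification genes 0 were bound, with an upper exact bound of 15.4%. No entry of the pooled list had its summit in the promoter window of sod-3, a superoxide dismutase gene often used as a DAF-16 reporter. The metallothionein gene mtl-1 had an entry at rank 15619 of 30000 in the pooled list, below the optimal threshold, skn-1 one at rank 2764 and daf-2 one at rank 12718. Of the genes whose sequence the transgene or its insertion may carry, ges-1 had an entry at rank 16197, unc-119 at rank 11421, and daf-16 had none in its window.

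The other families did not pass the test in the optimal set. Bound genes numbered 4 of 156 collagens (adjusted exact p = 0.701), 9 of 269 nuclear hormone receptors (0.792), 4 of 74 cytochromes P450 (0.792), 5 of 67 UDP-glucuronosyltransferases (0.428), 2 of 44 glutathione S-transferases (0.792), 3 of 50 histones (0.729), 0 of 16 lysozymes (1), 2 of 33 proteasome subunits (0.792) and 2 of 38 insulin-like peptides (0.792), with adjusted exact p values in brackets. Without replicate 2 the histone ratio went from 1.44 to 3.43 and passed (adjusted exact p = 0.0171). These tests count genes as independent, but neighbours can share a peak. In the optimal set his-61 and his-62 shared a peak, as did cyp-33C6 and cyp-33C7. Of the 4 bound collagen genes, col-185, col-85 and col-54 had peaks by transfer RNA genes.

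Because the transgene is expressed from an intestinal promoter, the intestine list was set against lists of other tissues. Of 47 intestinal genes 6 were bound, 12.8%, against 2 of 198 genes of neurons, muscle, hypodermis and germline, 1.01% (Fisher's exact test, two-sided, p = 7.75e-04). This 12.64-fold difference was 5.62-fold with 2000 bp upstream, with 8 and 6 bound (exact p = 0.00127), and 25.3-fold with 500 bp, with 6 and 1 bound (exact p = 2.27e-04). The 1.01% of the other tissues was itself below the 4.19% of all protein-coding genes. Against all other genes the intestine ratio was 3.065. The bound intestinal genes included elt-2, the GATA factor that governs intestinal genes, with a signal of 173.2 and its summit 477 bp from a transcript start on chromosome X, from 10480553 to 10480972. They also included vit-2 with 130.7, the intestinal actin gene act-5 with 93.29 and the cathepsin B-like gene cpr-6 with 91.74. In the other tissues 0 of 49 neuronal (adjusted p against all other genes 0.484), 1 of 49 muscle (unc-60, 0.792), 0 of 46 hypodermal (0.484) and 1 of 54 germline genes (cgh-1, 0.792) were bound. In the higher-signal 744 peaks, 2 intestinal genes were bound and the difference from the other tissues, then 8.43-fold, no longer passed (p = 0.0951, Fisher's exact test).

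The X chromosome held 396 of the 1464 nuclear peaks, 27.05% with an exact interval from 24.8% to 29.4%, where it makes up 17.7% of the nuclear genome. The density was 22.3 peaks per Mb on X, and on the autosomes it ran from 10.6 on V to 16.98 on III. The ratio of X to autosomes was 1.73 (exact binomial test, two-sided, p = 5.81e-19). Of the X peaks, 166 were within 100 bp of a transfer RNA gene, and X carries 276 of the 612 nuclear transfer RNA genes. Among those on X 62.3% had a peak, and among those on autosomes 55.4% (Fisher's exact test, two-sided, p = 0.0842). Counting other peaks alone, X had 12.98 per Mb and III, the densest chromosome, 14.36.

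**Figure D4:**
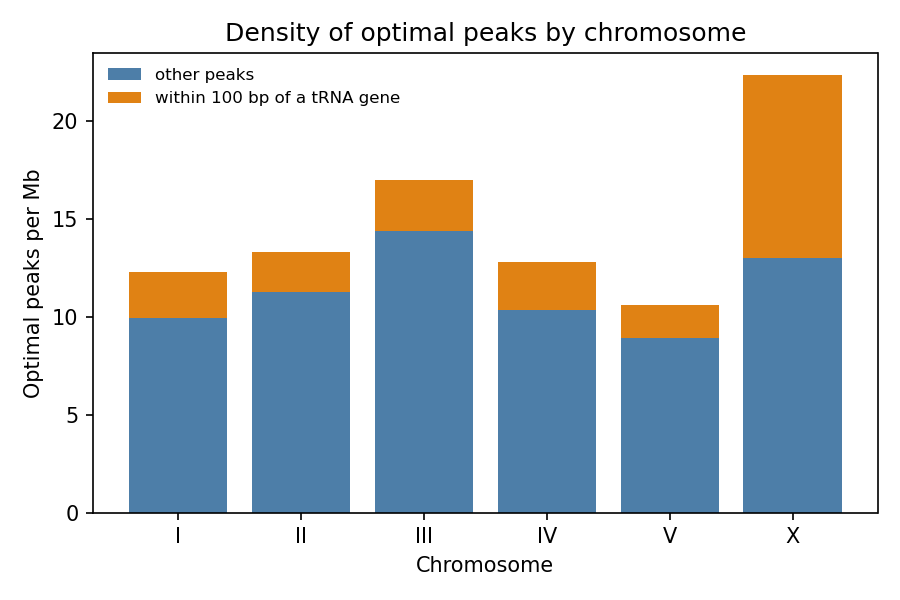
Optimal peaks per Mb (y axis) on each nuclear chromosome (x axis), split into peaks within 100 bp of a transfer RNA gene and other peaks. X stood at 22.3 per Mb, of which 9.37 were by transfer RNA genes.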

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

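The test of mitochondrial coverage was chosen after the result was seen. The 25 optimal entries on the mitochondrial chromosome were picked out because they hold the highest signals of the set. They are counted among the 1489 summits of the promoter comparison, and with nuclear peaks only the excess there was 1.55-fold as well. They fell in 5 intervals that covered 89.7% of the 13794 bp chromosome, and 25 of the replicate 1 and 22 of the replicate 2 highest-signal entries were mitochondrial too. Coverage of most of the chromosome is consistent with more mitochondrial DNA in the immunoprecipitated libraries than in the control, since sites of one factor would be expected at few places. The control library was not analysed here, so its mitochondrial share stays unknown, and no biological explanation was tested.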

How the results depend on the processing

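The alternatives without mitochondrial entries, without peaks at transfer RNA or all small RNA genes and with other flank draws were chosen after the data were seen. No paired analysis was possible because the series has 1 group. The replicate overlap ran from 53.4% to 74.2%, the rank correlation from 0.581 to 0.608, the promoter excess from 1.204-fold to 1.76-fold and the X ratio from 1.21, without peaks at transfer RNA genes, to 2.34, all past their tests. Without those peaks the sets of single replicates gave 1.161 and 1.186. The TGATAAG excess ran from 2.82-fold to 7.15-fold and was 1.77-fold for TGATAA, all past their tests. In the higher-signal part of the optimal set, with fewer peaks, the TRTTTAC excess was 1.59-fold and the intestine excess over other tissues 8.43-fold, both no longer past the threshold, 727 7-mers and 3 lists were enriched, and bound ratios were 0 for raised DAF-16 targets, 1.01 for collagens and 0 for UDP-glucuronosyltransferases, turned from the main direction. TRTTTAC within 25 bp gave 1.52-fold, no longer past the threshold, and 687 7-mers. At promoter summits, with promoters of genes with no peak as background, 245 7-mers were enriched, and without peaks at small RNA genes 613. The cause of these changes was not tested. The higher-signal part has fewer peaks, and a larger share of them lay by transfer RNA genes. Ratios of lists that did not pass the test also turned. Leaving out a replicate gave 0 to 1.49 for lysozymes, 0.628 to 0.640 for insulin-like peptides, 0 to 1.11 for antioxidant genes, 0.657 to 1.29 for cytochromes P450 and 0.738 to 1.45 for proteasome subunits. Without peaks at small RNA genes the ratios were 0.782 for cytochromes P450, 0.657 for glutathione S-transferases and 0.877 for proteasome subunits. With 500 bp upstream they were 0.429 for cytochromes P450, 0.964 for proteasome subunits and 0.837 for insulin-like peptides. With 2000 bp upstream neurons had 1.08, and by the nearest start histones had 0.822. By the nearest start, raised DAF-16 targets (3.26) and lipid metabolism (3.10) gained a call and autophagy and lysosome genes (3.12) lost it. With 2000 bp upstream lipid metabolism (3.99) and insulin-like signalling (4.43) gained one. Without replicate 2 histones (3.43) gained one and C-type lectins (0.306) and the intestine list (2.60) lost it. In the higher-signal part autophagy and lysosome genes (1.59), the intestine list (2.24) and C-type lectins (0.439) lost it, as the intestine list did against matched lists (3.08). The lists hold no read counts, so what depth limits is unknown.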

Other observations

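The tests of TRTTTAC and TGTTTAC at transfer RNA genes and of X without transfer RNA genes, the density by chromosome, and the comparison of high with low signals, were chosen after the results were seen. Peaks by small RNA genes stood high in the ranking. Of the 366 nuclear peaks with the highest signal, 139 lay by transfer RNA genes and 44 by small nucleolar RNA genes, and of the 366 with the lowest 47 and 6 did (Fisher's exact test, adjusted p = 2.00e-14 and 2.87e-08). Promoter windows held 140 summits among the highest and 202 among the lowest (Fisher's exact test, adjusted p = 9.87e-06). From the highest to the lowest signals, in 4 sets of 366, TGATAAG was at 19, 36, 46 and 28 summits. The first and last of these were compared (exact test, adjusted p = 0.227) and the middle sets were not tested. TRTTTAC was at 29 summits of the first and 13 of the last (exact test, adjusted p = 0.0202).

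The peaks at transfer RNA genes were set against a pair of technical explanations. Reads shared between identical gene copies would leave genes of unique sequence nearly without peaks, but 39.2% of the 143 transfer RNA genes of unique sequence had one, with an exact interval from 31.1% to 47.7%, where random positions gave 0.401%. Genes with an identical copy had a higher share, 64.4% of 469 (Fisher's exact test, p = 1.27e-07), so shared reads may still add to part of the pattern. Unique here means without an identical copy, so reads shared between nearly identical genes were not tested. Capture without a DAF-16 site stays open: TRTTTAC at these peaks was 1.90-fold over the flanks (exact McNemar test, p = 0.0614, and under 0.05 in 193 of 1000 draws of the flank), and its share did not differ detectably from that at other nuclear peaks (Fisher's exact test, p = 0.682). The TGTTTAC form was more frequent than in the flanks, at 5.49% against 1.16% (exact McNemar test, adjusted p = 0.00214), but 16 of its 19 sites lay in transfer RNA gene sequence and 327 of the 346 peaks had none. No untagged sample was analysed here, and no biological explanation was tested.

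The X excess was set against 2 explanations. With peaks at transfer RNA genes left out, the ratio of X to autosomes was 1.21 (exact binomial test, p = 0.0121), down from 1.73. That test takes the autosomes as alike, and X, at 12.98 peaks per Mb, then lay between chromosomes V at 8.94 and III at 14.36, so transfer RNA genes as the whole cause stay open. More X DNA or more mappable X sequence might raise the weak entries too. X held 15.4% of the lower-ranked part of the pooled list, below its 17.7% of the genome, and 4782 of all 30000 entries. Stronger X signal could also move X entries out of the lower-ranked part. Neither read coverage nor mappability was measured here, so these shares do not exclude either explanation. No biological explanation was tested.

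A hypothesis that TGATAAG and TRTTTAC occur in the same summit windows was tested on nuclear peaks. Both were in 6 windows, with an odds ratio of 0.856 (Fisher's exact test, p = 0.840), which shows neither a joint occurrence nor an avoidance.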
